A study of Mus musculus with 12 samples.

How the data were processed

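RNA was measured in the liver of 12 mice, 3 females and 3 males of each of the strains KK/HIJ and C57BL/6J, with 1 Affymetrix whole-transcript array per mouse. Per the labels, the mice ate chow, were 8 weeks old, were housed singly for 3 days and went without food for 4 hours. They were killed by cervical dislocation and perfused with PBS, and the large liver lobe was kept in RNAlater for 24 hours before it was frozen. Biotin-labelled target was made from 300 ng of total RNA. The strain characteristic reads KK/HIJ, while another label of the same samples reads KK/J. Both are called KK below. The labels give no scan date, hybridisation batch or litter.

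The deposited values are log2 expression values, 1 per probe set and array. Per the labels, the authors made them with RMA and the affy package, and neither version is given. RMA as usually run corrects the background, equalises the distributions of the arrays and summarises the probes of a set. The distributions of the deposited values were not fully equal, with interquartile ranges of 2.64 to 2.97. A difference of 1 on the log2 scale is a doubling. The table holds 21212 probe sets, which are numbered by Entrez gene. No scanner files were available, so background correction was not repeated with other settings, detection calls could not be made, and single probes could not be examined. The level of absent transcripts was read instead from the 3 measured Y-linked genes in the 6 female arrays, which lay between 3.79 and 4.66 with a mean of 4.19.

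Gene symbols came from the platform's table of probe sets and were checked against the RefSeq annotation of the mouse genome build GRCm38.p6, which also gave the chromosome and the order of the genes. Exactly 1 symbol was found for 18786 probe sets, several for 6, and none for 2420, which stay unnamed here. These covered 18784 genes, of which 18775 were found in the RefSeq table.

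All 12 arrays were fitted together in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 mean per strain and sex. The fit had a prior of 3.99 and a total of 11.99 degrees of freedom. No probe set was left out. A total of 6 comparisons were made: KK minus C57BL/6J over both sexes, in females and in males; male minus female in C57BL/6J and in KK; and the interaction, which is the strain difference in males minus that in females. The mean of the sex differences of both strains was used for gene lists. Tests were two-sided. The p-values of each comparison were adjusted by the method of Benjamini and Hochberg over all probe sets, and a probe set was called at an adjusted p under 0.05. Adjusted p-values of single genes are limma's. Standard errors (SE) are those of the limma fit, SDs are over the 3 mice of a group, and n is 3 mice per group throughout.

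A total of 34 gene lists were written from general knowledge before the data were examined, as were the comparisons, the alternatives and the rule for naming genes. Of these lists, 3 served to check the labels and 31 were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists. Camera compares the genes of a list with all other genes. It was run again with an estimated correlation, and fry was run as a test of whether a list's genes moved, on balance, in 1 direction. Calls within a list were counted after adjustment over all probe sets and also adjusted over the list alone. Some genes stand in more than 1 list. Many of the markers of other cell types, as well as most genes of the metabolic lists, are also transcribed in hepatocytes to some degree.

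Only genes with exactly 1 symbol were named, through the brightest probe set, and predicted or unnamed genes were passed over. For the strain difference over both sexes these were the 10 largest differences each way among calls whose 6 KK values all lay above, or all below, their 6 C57BL/6J values. For each other comparison of groups they were the 5 largest each way among calls whose 3 values did not overlap those of the other group, which chance gives to 10% of genes at 3 mice against 3. For the interaction they were the 5 largest calls each way. Up to 4 members of each list with the smallest adjusted p in the strain comparison, or in the sex comparisons for the sex-biased lists, and all genes of the label checks were added. Genes named outside this rule were chosen after their values were seen, and the text says so.

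The alternatives were quantile or cyclic loess normalization of the deposited values, only probe sets above the median mean, 1 probe set per gene, an intensity trend with a robust prior, array weights, the replicate number as a block, a fold of at least 1.5, only the 2 groups compared, and each array left out in turn. The interquartile range of each array as a covariate was added after the data were seen. The pipeline was tested on simulated data with 200 changed probe sets per comparison, split between folds of 1.5, 2 and 4. Of the 67 changed 2-fold it recovered 100% for the strain difference, 95.5% for a sex difference in 1 strain and 80.6% for the interaction. Of the 67 changed 1.5-fold the interaction recovered 38.8%. Of all simulated calls, between 4.3% and 7.1% were false. The simulated noise was independent between probe sets and between arrays. It held none of the structure between the real arrays described below, so these rates may not hold for the real data. The number of animals limits the precision of every value. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.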

Results

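The series compared the liver transcriptome of KK mice, an inbred strain known for obesity and insulin resistance, with that of C57BL/6J mice, a widely used laboratory strain. The data were 12 arrays, 3 for each strain and sex. The median log2 value of the arrays lay between 5.9 and 6.03, and their interquartile range between 2.64 in KK male 2 and 2.97 in KK female 1. Across probe sets, which are not independent replicates, arrays of the same group correlated at 0.992 to 0.996 and arrays of different groups at 0.975 to 0.993. The largest principal component held 38.1% of the variance, and strain accounted for 80.6% of it. The next held 23.1%, and sex accounted for 69.3% of it. Another, with 13.9%, followed the interquartile range of the arrays (54.4%) and the replicate number in the sample titles (53.1%).

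The labels were checked with genes of known behaviour. Xist, the RNA that silences one X chromosome in females, was lower in males by -6.18 log2 over both strains (SE 0.10, adjusted p = 1.66e-12). All 3 measured Y-linked genes were called higher in males of each strain: over both strains Eif2s3y differed by 3.94, Uty by 3.48 and Kdm5d by 1.81. Of the 4 measured X-linked genes known to be higher in females, all were called lower in males over both strains, with Kdm6a at -0.77, Kdm5c at -0.41 and Ddx3x at -0.35. In C57BL/6J alone 1 of the 4 was called and in KK alone 4. By limma all 4 were lower at an unadjusted p under 0.05 in each strain. Nnt, a mitochondrial transhydrogenase that carries a deletion in C57BL/6J, was higher in KK by 0.97 (SE 0.05, adjusted p = 1.43e-07). H2-Ea, an MHC gene that C57BL/6J mice do not transcribe, lay near the background level in both strains and differed by -0.05 (adjusted p = 0.618).

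The strain difference over both sexes asks which transcripts set KK livers apart from C57BL/6J livers. Gstp3, a glutathione S-transferase gene on chromosome 19, was higher in KK by 5.08 log2 (SE 0.10, 33.8-fold), with a mean of 12.04 (SD 0.04) in KK females against 7.17 (SD 0.28) in C57BL/6J females. Akr1c18, which encodes an aldo-keto reductase that inactivates progesterone, was higher by 4.92 (SE 0.11, 30.3-fold). Vnn1, which encodes the pantetheinase that breaks down pantetheine and is a target of PPARalpha, fell by 3.90 (SE 0.12), from 10.23 (SD 0.34) to 6.38 (SD 0.16) in females and from 9.49 (SD 0.15) to 5.54 (SD 0.29) in males.

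The rule took the 10 largest named differences each way among calls whose 6 KK values did not overlap their 6 C57BL/6J values. Beside Gstp3 and Akr1c18, the increases were Cyp4a12a (4.04), Cap2 (3.71), the guanylate-binding protein gene Gbp11 (3.05), Serpina4-ps1 (2.98), Cyp2c39 (2.94), Gdpd3 (2.87), Rassf4 (2.83) and Asic5 (2.74). Besides Vnn1, the decreases held the carboxylesterase pseudogene Ces2d-ps (-4.23), Cyp39a1 (-3.13), an oxysterol hydroxylase of bile acid synthesis, the organic anion transporter gene Slco1a4 (-2.61), Akr1c12 (-2.61), the antitrypsin gene Serpina1d (-2.53) and a second vanin gene, Vnn3 (-2.24). Among them were also the probe sets of 3 genes with general cellular roles: the translation initiation helicase gene Eif4a1 (-4.02, SE 0.22), the mRNA export gene Sarnp (-3.91, SE 0.23) and the actin capping gene Capza1 (-3.41, SE 0.36). Eif4a1 and Sarnp lay near the background level in KK, at 4.70 (SD 0.50) and 4.10 (SD 0.53) in females. Values of Gstp3, Akr1c18, Akr1c12, Cyp4a12a, Serpina1d, Ces2d-ps and Gbp11 are uncertain as to the gene, since close paralogs share much of their sequence. Named calls of comparable size whose values overlapped, given after they were seen, were Cyp4a12b (3.76), Cyp4a14 (-3.94), Cyp17a1 (-3.06) and Cyp2b13 (-2.57). In all, limma called 2488 of 21212 probe sets (11.7%), 1149 higher and 1339 lower in KK. At least 2-fold differences were found for 183 of them, 82 higher and 101 lower. The lower calls outnumbered the higher ones only as deposited: they made up 53.8% of calls, but 48.9% after quantile and 49.6% after loess normalization.

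**Figure D1:**
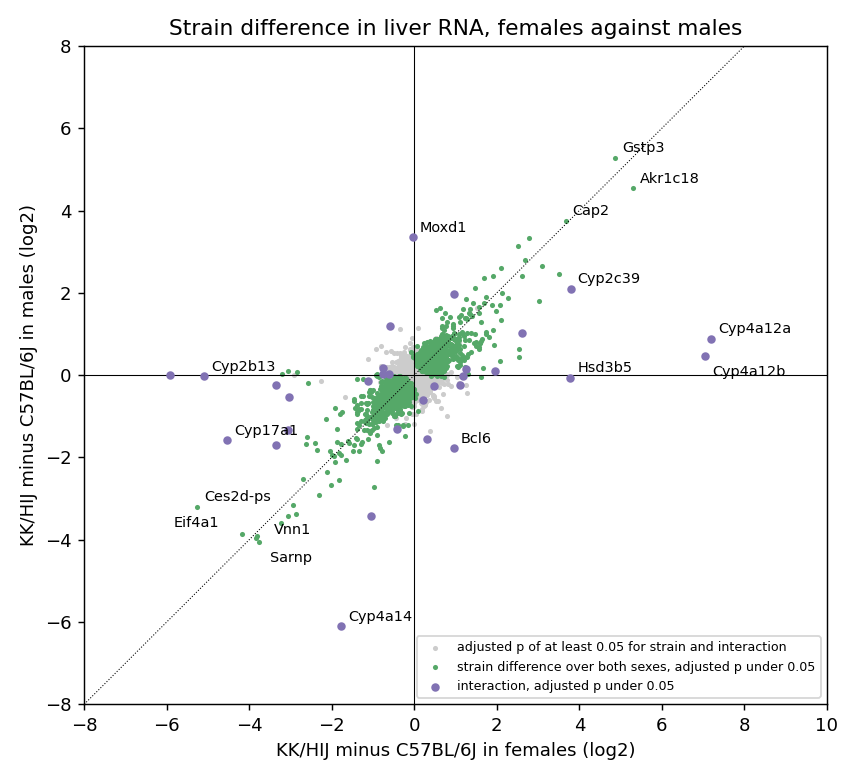
Strain difference of each probe set (KK minus C57BL/6J, log2) in females on the horizontal and in males on the vertical axis, with points coloured by the limma calls for strain over both sexes and for the interaction. Gstp3, Akr1c18 and Cap2 lie near the dotted line of equal differences, while Cyp4a12a (7.19 in females and 0.88 in males) and Cyp4a14 (-1.78 and -6.11) lie far from it.

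Of 26 genes of fatty acid and triglyceride synthesis, 7 rose and 2 fell in KK, and 17 were not called (11 were called when adjusted over the list alone). Those that rose included Thrsp (1.42), Acacb (0.93), which makes the malonyl-CoA that restrains fatty acid oxidation, and the desaturase and elongase genes Fads1 (0.48) and Elovl5 (0.64). The list's adjusted p by camera was 0.0294, against an adjusted p = 0.455 with an estimated correlation, and it was 0.0516 without C57BL/6J male 2 and 0.0813 without KK male 1. Of 19 genes of cholesterol synthesis and SREBP2 targets, 7 fell and 1 rose (11 adjusted over the list alone): Sc5d (-1.07), Pmvk (-0.81), Ggps1 (-0.72) and Tm7sf2 (-0.56) fell, and Dhcr7 (0.43) rose. By camera the adjusted p was 3.6e-06, and 0.461 with an estimated correlation. Of 27 genes of fatty acid oxidation and PPARalpha targets, 9 fell and 2 rose (13 adjusted over the list alone). Beside Vnn1, the omega-hydroxylase genes Cyp4a14 (-3.94), Cyp4a10 (-2.23) and Cyp4a31 (-1.85) fell most. Camera gave an adjusted p of 7.28e-05, against 0.465 with an estimated correlation. The 2 that rose, Acaa1b (0.26) and Pex11a (0.32), which like Dhcr7 were named after their values were seen, gave a count of 0 or 1 without any one array other than C57BL/6J female 3, C57BL/6J male 3 and KK female 3. Of 18 PPARgamma targets and lipid droplet genes, 3 rose, with Mogat1, a monoacylglycerol acyltransferase gene, at 1.47, and 1 fell, the fatty acid transporter gene Cd36 (-0.77). Adjusted over the list alone 5 were called, and the adjusted p was 0.339 by camera and 0.043 by fry. In this list 1 gene rose without C57BL/6J female 1, female 3, male 2 or male 3, or KK female 1 or female 2, and 3 fell without C57BL/6J male 2.

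Of 24 genes of bile acid synthesis and transport, 10 fell and 4 rose (14 adjusted over the list alone), with the bile salt export pump gene Abcb11 at -1.01 (SE 0.05), the bile acid CoA ligase gene Slc27a5 at -0.64 and Hsd3b7 at -0.43. Camera gave an adjusted p of 0.000262, against 0.455 with an estimated correlation. Of 27 genes of lipoprotein and HDL metabolism, 7 fell and 5 rose (15 adjusted over the list alone), and the adjusted p by camera was 0.339. The sterol exporter genes Abcg5 (-0.85) and Abcg8 (-0.86) and Apom (-0.66) fell, while Apoa4, an apolipoprotein gene induced by hepatic lipid load, rose by 2.35 (SE 0.09). Without C57BL/6J male 2 or without KK female 2, 3 genes of this list rose, and its median of -0.04 became 0.01 after loess normalization.

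Of 20 NRF2 target and glutathione genes, 7 rose and 1 fell (9 adjusted over the list alone). Gstm3 (0.77), Gstm2 (0.63), Gsta4 (0.37) and Gstm4 (0.32) rose, and the carbonyl reductase gene Cbr1 (-0.52), named after its value was seen, fell. The adjusted p was 0.0117 by camera and 0.455 with an estimated correlation. Of 18 CAR, PXR and AHR target genes, 7 fell and 3 rose (12 adjusted over the list alone), with Ces2a at -1.94, Cyp2c37 at -1.2 and the receptor gene Ahr at -0.53. The adjusted p by camera was 0.101, but 0.0442 without C57BL/6J female 2 and 0.0482 without KK male 3. By fry the adjusted p was 0.0132. The count of 3 was 1 without C57BL/6J female 2 or male 3, or KK female 1, female 3, male 1, male 2 or male 3.

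Of 26 acute phase genes, 6 rose and 0 fell (8 adjusted over the list alone), and limma gave 10 an unadjusted p under 0.05, all of them higher in KK. Apcs, which encodes serum amyloid P, rose by 2.15 (SE 0.09), Lcn2 by 1.5, Lbp by 0.83 and Saa4 by 0.71. For this list camera gave an adjusted p of 0.00137, against 0.558 with an estimated correlation. Of 25 interferon response genes, 12 fell and 13 were not called (17 adjusted over the list alone), with Usp18 at -1.44 (SE 0.17), Bst2 at -0.91, Rsad2 at -0.78 and the RNA sensor gene Ifih1 at -0.62. Their adjusted p was 2.3e-09 by camera and 0.455 with an estimated correlation. Without C57BL/6J female 1, KK male 1 or KK male 2 the count was 7 each time. Of 23 MHC class I and class II genes, 7 fell and 3 rose (11 adjusted over the list alone). The class Ib genes H2-T22 (-2.03), H2-T23 (-1.86) and H2-Q7 (-1.47) fell and H2-T10 (1.48) rose, but H2 genes are highly polymorphic and similar to each other, so these values are uncertain as to the gene. The adjusted p was 0.00173 by camera and 0.558 with an estimated correlation, and 1 gene of this list rose without any one array other than C57BL/6J female 3, C57BL/6J male 1, KK male 1 and KK male 3.

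Of 25 genes of the mitochondrial respiratory chain, 8 fell and 1 rose (12 adjusted over the list alone), all by small amounts: Ndufa9 by -0.45, Cox6c by -0.34 and Sdhd by -0.26, while Sdhc differed by 0.26. By camera the adjusted p was 2.25e-05, and 0.455 with an estimated correlation. Without any one array other than C57BL/6J female 3 and KK female 3, 4 or 5 genes of the mitochondrial respiratory chain fell. In the growth hormone and IGF axis, 3 of 13 genes rose and 2 fell (6 adjusted over the list alone): Igfbp2 fell by 2.14 (SE 0.15), Stat5b by 0.31, and Igfbp3 (1.09) and Onecut1 (1.06) rose. The list's median of 0.02 and its mean of -0.02 differed in sign, and its adjusted p by camera was 0.992. In glucose metabolism and insulin signalling, 3 of 23 genes fell and 1 rose (9 adjusted over the list alone), among them the glycogen synthase gene Gys2 (-0.50) and the pyruvate carboxylase gene Pcx (0.32), at an adjusted p of 0.874 by camera. The median of this list, -0.01, turned sign with scaling. Of 15 genes of iron homeostasis, 3 rose and 1 fell (5 adjusted over the list alone): the hepcidin gene Hamp rose by 1.25 and its upstream regulator Hjv fell by 1.07, at an adjusted p of 0.474 by camera. In the circadian clock 2 of 18 genes rose and 1 fell (4 adjusted over the list alone), with Bhlhe41 at 0.47, Per2 at 0.38 and Nr1d1 at -0.36, at an adjusted p of 0.101 that was 0.0356 without C57BL/6J female 3 and 0.0183 without C57BL/6J male 3. In cell proliferation 1 of 20 genes rose and 2 fell (5 adjusted over the list alone), with Ccnd1 at -0.88, Mcm6 at -0.40 and Tyms at 0.28, at an adjusted p of 0.941; its median of 0.01 and mean of -0.03 differed in sign. In the unfolded protein and integrated stress response 1 of 20 genes was called, Dnajb9 (0.49, adjusted p = 0.0288), and 0 when adjusted over the list alone, at an adjusted p of 0.669 by camera. Dnajb9 had an adjusted p between 0.0549 and 0.0723 without C57BL/6J female 1, female 2 or male 2, or KK female 1, female 3 or male 3.

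Lists of hepatocyte zones and of other cell types were tested as well. Of 14 pericentral hepatocyte genes, 4 fell and 1 rose (7 adjusted over the list alone), with Slc1a2 at -0.49 and Rhbg at 0.44. The adjusted p was 0.041 by camera and 0.465 with an estimated correlation, and it was between 0.0501 and 0.088 without C57BL/6J female 2, C57BL/6J male 1, KK female 2, KK male 1 or KK male 2. Of 12 periportal hepatocyte genes, 3 rose and 3 fell (7 adjusted over the list alone), with Etnppl at 0.71 and Hal at -0.41, at an adjusted p of 0.992. Of 7 erythroid and neutrophil markers 3 rose, among them Alas2, the erythroid heme synthesis gene (1.19; 3 adjusted over the list alone), and the list's adjusted p was 0.00173 by camera and 0.231 with an estimated correlation. Of 17 Kupffer cell and macrophage markers 3 fell and 1 rose (4 adjusted over the list alone), with Marco at -0.75, at an adjusted p of 0.15 that was 0.049 without C57BL/6J male 1, 0.00459 without KK female 1 and 0.0411 without KK male 3. In this list 6 genes fell without KK female 1, and 1 without C57BL/6J female 1, female 2 or male 2, or KK female 2, female 3, male 1 or male 2. The gene that rose, Itgam (0.33, adjusted p = 0.0361), had an adjusted p of 0.0515 after quantile and 0.06 after loess normalization, and of 0.0569 to 0.0857 without any one array other than C57BL/6J male 2 and the 3 KK females, and 2 genes rose without KK female 3. Of 15 sinusoidal endothelial markers 3 fell and 1 rose (5 adjusted over the list alone), with Lyve1 at -0.74, at an adjusted p of 0.0933 that was 0.0483 without C57BL/6J female 2, 0.0393 without C57BL/6J male 1, 0.00255 without KK female 1 and 0.0281 without KK male 3. Of 18 stellate cell and fibrosis genes 3 fell and 1 rose (4 adjusted over the list alone), with Lum at -0.64 and Rgs5 at 0.90, at an adjusted p of 0.339. Of 9 cholangiocyte markers 1 rose, Slc4a2 (0.32), and 1 fell, Pkhd1 (-0.22, adjusted p = 0.0492; 3 adjusted over the list alone), at an adjusted p of 0.992. Pkhd1 had an adjusted p of 0.0622 to 0.107 without any one array other than C57BL/6J female 2 and KK female 1. The gene Car3, also abundant in hepatocytes, was the only one called among 7 white adipose tissue markers (-0.29; 1 adjusted over the list alone; list adjusted p of 0.841). By limma 0 of 14 T cell and NK cell markers were called (1 at an unadjusted p under 0.05; list adjusted p of 0.874), 0 of 8 B cell and plasma cell markers (2 unadjusted; 0.339) and 0 of 9 exocrine pancreas markers (1 unadjusted; 0.874).

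In females, the largest named strain difference was that of a male-biased gene. Cyp4a12a, a fatty acid hydroxylase gene normally expressed in males, was higher in KK females by 7.19 log2 (SE 0.21), with a mean of 12.25 (SD 0.11, n = 3) against 5.06 (SD 0.49, n = 3) in C57BL/6J females. Its near-identical neighbour Cyp4a12b was higher by 7.05 (SE 0.18), and the probes may read either gene. Cyp2b13, a cytochrome P450 gene normally expressed in females, fell by 5.11 (SE 0.35), and the steroid hydroxylase gene Cyp17a1 fell by 4.53 (SE 0.35). Akr1c18 (5.30), Gstp3 (4.87) and Cyp2c39 (3.79) were the other 3 of the 5 largest named increases, and Ces2d-ps (-5.27), Eif4a1 (-4.17) and Vnn1 (-3.85) the other 3 of the 5 largest named decreases.

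Of 18 male-biased liver genes, 10 rose and 0 fell in KK females (14 adjusted over the list alone; median 0.87), and of 18 female-biased liver genes, 10 fell and 0 rose (12 adjusted over the list alone; median -1.57). Hsd3b5, a steroid dehydrogenase gene, rose by 3.77, the complement gene C6 by 2.54, the transporter gene Slco1a1 by 2.07 and the urinary protein gene Mup20 by 1.96. Among female-biased genes the sulfotransferase gene Sult3a1 fell by 3.21, Cyp3a16 by 3.07 and Slc22a26 by 2.83, and Abcd2 differed by -2.37. Other members were not called, among which Cyp2u1 differed by 0.02 (adjusted p = 0.988), Gstp1 by -0.14 (adjusted p = 0.673) and A1bg by -0.83 (SE 0.85, adjusted p = 0.759), with an SD of 2.48 among KK females. Of the 15 male-biased genes that were called between the sexes of C57BL/6J, KK females lay on the male side of the midpoint between the C57BL/6J sexes for 7, on the female side for 4 (Elovl3, Gstp1, Susd4 and Cyp2u1) and on neither by limma for 4. C57BL/6J females enter both of these differences. C6, Slco1a1, Mup20, Sult3a1, Cyp3a16 and Susd4 were named after their values were seen. Over both sexes the male-biased list had 11 increases and 1 decrease (12 adjusted over the list alone; adjusted p 8.51e-09 by camera and 0.455 with an estimated correlation), and the female-biased list had 9 decreases and 0 increases (11 adjusted over the list alone; adjusted p 2.94e-07 by camera and 0.455 with an estimated correlation). In females limma called 1378 probe sets, 675 higher and 703 lower, and 905 without KK female 1. Which side was larger turned with quantile (875 higher, 802 lower) and loess normalization (857 and 784), without C57BL/6J female 3 (500 and 432) and without KK female 2 (546 and 470).

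**Figure D2:**
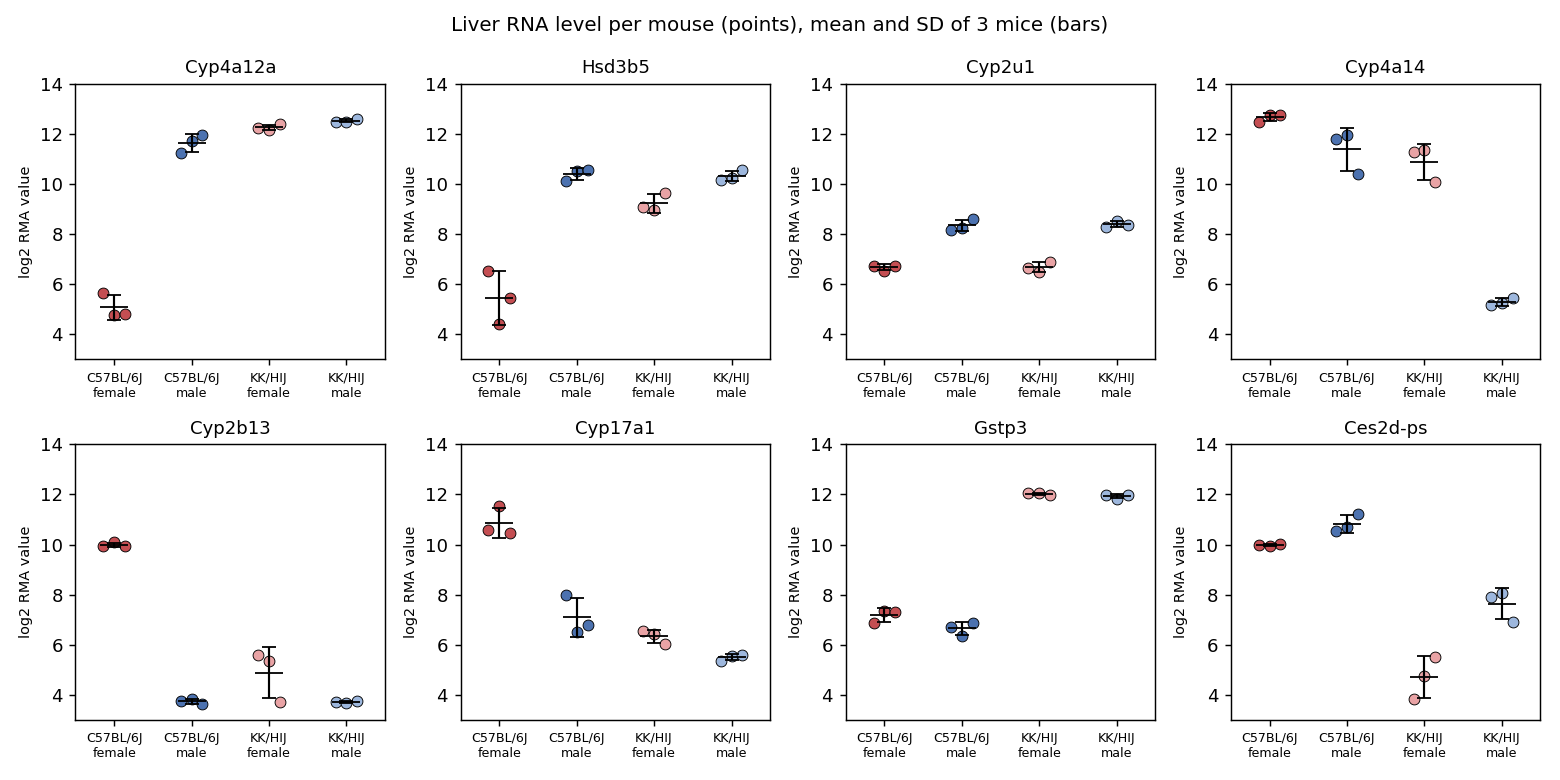
Log2 RMA value of 8 genes in each of the 12 mice (points), with the mean and SD of the 3 mice of each group (bars). Mean values of Cyp4a12a are 12.25 in KK females and 11.64 in C57BL/6J males, and those of Cyp2u1 6.68 in KK females and 6.66 in C57BL/6J females.

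In males, the largest named strain difference was a decrease. Cyp4a14, an omega-hydroxylase gene of fatty acid metabolism, fell by 6.11 log2 (SE 0.38), from 11.38 (SD 0.85, n = 3) in C57BL/6J to 5.27 (SD 0.15, n = 3) in KK males, and its neighbours Cyp4a10 (-3.43) and Cyp4a31 (-2.73) fell too. Moxd1, a monooxygenase-like gene known as male-biased, rose by 3.35 (SE 0.29) from near background, 4.82 (SD 0.28) in C57BL/6J males, to 8.17 (SD 0.80). Gstp3 (5.29), Akr1c18 (4.54), Cap2 (3.75) and Gbp11 (3.32) were the other 4 of the 5 largest named increases, and Sarnp (-4.05), Vnn1 (-3.95), Eif4a1 (-3.87) and Capza1 (-3.60) the other 4 of the 5 largest named decreases. The transcriptional repressor gene Bcl6, male-biased in C57BL/6J, fell in KK males by 1.78.

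Among fatty acid oxidation and PPARalpha targets 8 of 27 fell and 1 rose in males (11 adjusted over the list alone), with Acot1 at -1.18 and Ehhadh at -0.78, both named after their values were seen. Without C57BL/6J female 1, for example, 0 rose in males. In females 7 fell and 2 rose (13 adjusted over the list alone), and 0 or 1 rose without any one array other than C57BL/6J male 2, KK female 3 and KK male 3. In interferon response 7 of 25 genes fell in males (12 adjusted over the list alone; 12 fell without C57BL/6J male 1) and 7 in females (8 adjusted over the list alone; 3 or 4 fell without C57BL/6J female 1 or 3, or KK female 2 or 3). Beside these, the Kupffer cell and macrophage markers had a median of -0.61 in males, and 2 of 17 were called, Clec4f (-0.75) and Csf1r (-0.75), the latter named after its value was seen (8 adjusted over the list alone; 10 at an unadjusted p under 0.05, all lower). The count was 0 without C57BL/6J male 2, KK male 1 or KK male 2, 1 without C57BL/6J female 1, female 3 or male 3, 4 without KK female 3 or KK male 3 and 6 without KK female 1, and the median was -0.33 without C57BL/6J male 2. In females the median of these markers was 0.19, and it ranged from -0.046 to 0.373 in single omissions of an array. Of 23 MHC class I and class II genes 7 fell and 1 rose in males (9 adjusted over the list alone; 4 fell without C57BL/6J male 2 or KK male 1). Of the male-biased liver genes 2 rose and 1 fell in males (3 adjusted over the list alone; median 0.07; 1 rose without C57BL/6J male 1 or 2 or any one KK male), and of the female-biased genes 2 fell and 0 rose (2 adjusted over the list alone; median -0.05; 1 fell without KK male 1 or 2). In males limma called 1092 probe sets, 442 higher and 650 lower (59.5%), a share that was 51.9% after quantile and 52.0% after loess normalization. The count was 662 without KK male 1 and 711, with 349 higher and 362 lower, without C57BL/6J male 3.

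The strain differences of the sexes, which share no array, were compared with each other. Across probe sets, which are not independent replicates, Pearson's r was 0.650 and Spearman's rho 0.401. A total of 659 probe sets were called in both sexes, of which 657 had the same direction, against 35.6 if calls and directions were independent. Both comparisons use the same spread per probe set, which can make the figure of 35.6 too low. The 2 with opposite directions, named after their values were seen, were Bcl6 (0.95 in females and -1.78 in males) and the Cyp4a gene Cyp4a32 (0.53 and -0.63), whose neighbours share its sequence. The call of Bcl6 in females had an adjusted p of 0.0191, and of 0.0708 to 0.0769 without C57BL/6J female 2, C57BL/6J female 3 or KK female 3. The adjusted p of Cyp4a32 was 0.0454 in females and 0.0214 in males. In females it was 0.0548 to 0.174 without any one array other than C57BL/6J male 2, KK female 3 and KK male 3, and in males 0.0538 to 0.0988 without C57BL/6J male 2 or 3 or KK male 1 or 2. Of the probe sets called in females 94.1% had the same sign in males, and of those called in males 96.0% had the same sign in females.

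The sex difference in C57BL/6J asks which liver transcripts depend on sex in the reference strain. Males had more of the fatty acid hydroxylase genes Cyp4a12b (6.92, SE 0.18) and Cyp4a12a (6.57, SE 0.21) and of the steroid dehydrogenase gene Hsd3b5 (4.94, SE 0.40, from 5.44, SD 1.07, to 10.38, SD 0.25). Females had more of Cyp2b9 (-6.44, SE 0.51), Cyp2b13 (-6.25), the transporter gene Slc22a26 (-6.10), Xist (-5.96) and A1bg (-5.62), with values given as male minus female. Cyp2b9 and Cyp2b13 are similar in sequence. The Y-linked genes Eif2s3y (4.10) and Uty (3.66) completed the 5 largest named increases.

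Of the male-biased liver genes 15 of 18 were called higher in C57BL/6J males (17 adjusted over the list alone; median 1.99), and of the female-biased liver genes 14 of 18 were called lower (16 adjusted over the list alone; median -2.78). Bcl6, a repressor known to be higher in male liver, was higher by 2.69, Elovl3 by 3.17 and C6, named after its value was seen, by 3.01. Fewer calls fell in other lists. Among 27 fatty acid oxidation and PPARalpha targets 3 fell in males and 0 rose, the acyl-CoA thioesterase genes Acot2 (-0.75), Acot3 (-1.67) and Acot4 (-1.45), named after their values were seen (10 adjusted over the list alone). The count was 6 without C57BL/6J female 1 and 1 without C57BL/6J female 2, female 3, male 1 or male 3. By limma 0 of 17 Kupffer cell and macrophage markers were called (3 at an unadjusted p under 0.05; 0 adjusted over the list alone; median -0.32, but -0.209 without C57BL/6J male 1 and -0.504 without C57BL/6J male 2). In all 219 probe sets were called, 76 higher and 143 lower in males, and 142 without C57BL/6J male 3.

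The sex difference in KK poses the same question in the other strain. Moxd1 was higher in KK males by 3.82 log2 (SE 0.29) and Ces2d-ps by 2.93 (SE 0.37), beside the Y-linked genes Eif2s3y (3.78) and Uty (3.31) and the elongase gene Elovl3 (2.0). Lower in KK males were Xist (-6.39), Cyp4a14 (-5.61, SE 0.38), Cyp2b9 (-5.28, SE 0.51), A1bg (-4.95, SE 0.85) and Slc22a26 (-3.19, SE 0.51). Values of A1bg varied widely among KK females (SD 2.48), and its adjusted p of 0.011 was 0.0535 without KK female 1 and 0.0893 in a fit of the KK groups alone. In that fit the adjusted p of Slc22a26 was 0.0739.

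Kupffer cell and macrophage markers were lower in KK males: 13 of 17 fell and 0 rose (15 adjusted over the list alone; median -1.07). The complement receptor gene Vsig4 fell by 1.58 (from 10.35, SD 0.44, to 8.77, SD 0.27), the lysozyme gene Lyz2 by 1.40, Cd163 by 1.2 and the Kupffer cell lectin gene Clec4f by 0.98. All but Clec4f were named after their values were seen. The count was 5 without KK female 1, 4 without KK male 1 and 4 without KK male 2. The medians of the list per array, relative to the mean of all arrays, were 0.81, 0.29 and 0.07 in KK females and -0.76, -0.75 and -0.43 in KK males. The median difference was -0.26 for the 15 sinusoidal endothelial markers, of which 2 fell (6 adjusted over the list alone), and -0.15 for the 18 stellate cell and fibrosis genes, of which 1 fell (4 adjusted over the list alone). Those called were Stab2 (-0.40), Fcgr2b (-0.50) and Ecm1 (-1.001), of which Stab2 and Ecm1 were named after their values were seen. The sinusoidal count was 0 without KK female 1, KK male 1 or KK male 2 and 1 without KK female 3, with a median of -0.156 without KK female 1. The stellate count was 0 without any one array other than C57BL/6J female 2, C57BL/6J male 2, KK female 3 and KK male 1.

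Other groups differed beside these markers in KK. Of 27 fatty acid oxidation and PPARalpha targets 10 fell in males and 0 rose (13 adjusted over the list alone), with Cyp4a10 at -2.95, Cyp4a31 at -2.34 and Cyp4a32, named after its value was seen, at -1.39. The count was 4 without KK female 1, KK female 2, KK male 1 or KK male 2. Of 18 male-biased liver genes 8 rose (12 adjusted over the list alone; median 0.94), with Cyp2u1 at 1.71 and Gstp1 at 1.49. The count was 5 without any one of KK female 1, KK female 2 and the 3 KK males. Of 18 female-biased liver genes 6 fell (14 adjusted over the list alone; median -0.81), with Abcd2 at -2.03. The count was 3 without KK female 1 and 10 without KK female 3. In all limma called 460 probe sets, 148 higher and 312 lower in males. The count was 160 without KK female 1, 193 without KK male 2 and 201 without KK male 1.

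**Figure D3:**
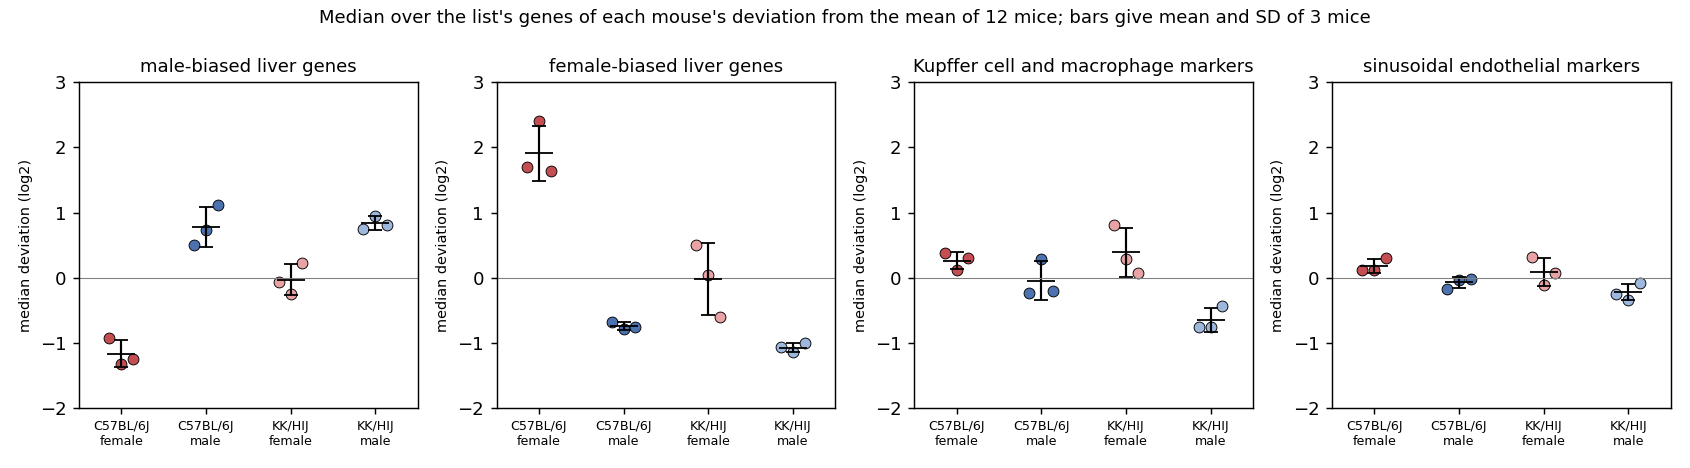
Median over the genes of 4 lists of each mouse's deviation from the mean of the 12 mice (log2, points), with the mean and SD of the 3 mice of each group (bars). Kupffer cell and macrophage markers lie between -0.76 and -0.43 in KK males and between 0.07 and 0.81 in KK females.

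Both sex differences had 105 calls in common, all in the same direction, against 2.6 if calls and directions were independent. The shared spread per probe set can make that figure too low. Pearson's r across probe sets was 0.522 and Spearman's rho 0.296. Over both strains camera passed 18 of 31 lists for sex, of which the male-biased and the female-biased liver genes also passed with an estimated correlation (adjusted p = 0.0332 for each). Of the male-biased genes 16 of 18 were called higher in males over both strains (18 adjusted over the list alone), and of the female-biased genes 14 of 18 lower (16 adjusted over the list alone). Kupffer cell and macrophage markers had a median male minus female difference of -0.69 over both strains, with an adjusted p of 6.08e-17 by camera and 0.197 with an estimated correlation. Sinusoidal endothelial markers had a median of -0.27, with an adjusted p of 2.84e-11 by camera and 0.207 with an estimated correlation.

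The interaction asks which strain differences depend on sex. Cyp4a12b (-6.59, SE 0.26) and Cyp4a12a (-6.31, SE 0.30) had the largest negative values among named genes: their strain differences were 7.05 and 7.19 in females against 0.46 and 0.88 in males. Hsd3b5 (-3.84, SE 0.56) and Bcl6 (-2.73, SE 0.30) followed the same direction, and Cyp4a14 (-4.33, SE 0.54) had its larger fall in males. Positive values belonged to the female-biased P450 genes Cyp2b13 (5.08, SE 0.49), Cyp2a22 (3.09, SE 0.31) and Cyp17a1 (2.96, SE 0.49), to Moxd1 (3.40, SE 0.42), which was high in KK males alone, and to the proton pump subunit gene Atp6v0d2 (2.51, SE 0.14). Cyp2b13 lay between 3.64 and 3.82 in males of both strains, at the background level, so a fall in males could not have been seen. The test of Cyp17a1 was near the threshold (adjusted p = 0.0458). It missed it in 4 alternatives, with an adjusted p of 0.054 to 0.0739, and without any one array other than C57BL/6J male 1, with up to 0.144. The adjusted p of Hsd3b5 was 0.0174, but 0.0508 with an intensity trend and robust prior, and 0.0534 to 0.066 without C57BL/6J female 3, male 2 or male 3, or KK male 1 or male 2.

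Of the male-biased liver genes 4 had a called negative and 1 a called positive interaction (15 adjusted over the list alone; median -1.005), and of the female-biased genes 2 a positive and 0 a negative one (9 adjusted over the list alone; median 1.02). The adjusted p by camera was 1.44e-24 and 2.66e-12, and adjusted p = 0.165 with an estimated correlation for each; fry gave 0.0149 and 0.0781. The count of 4 was 2 without C57BL/6J male 2, C57BL/6J male 3, KK male 1 or KK male 2. For the female-biased liver genes the count of 2 was 5 without KK female 1 and 1 without C57BL/6J female 1, female 2, male 2 or male 3, KK female 2 or any one KK male. Their median was 0.504 without KK female 3. In the growth hormone and IGF axis 2 genes were called, Bcl6 and the growth hormone target gene Cish (1.79, adjusted p = 0.0184), which was 7.42 (SD 0.38) in C57BL/6J females and 7.83 (SD 0.32) in KK males against 6.63 (SD 0.17) in C57BL/6J males and 6.83 (SD 0.12) in KK females. Cish, named after its values were seen, had an adjusted p of 0.0576 to 0.0714 without C57BL/6J male 2, C57BL/6J male 3, KK female 1 or KK male 2. By limma 0 of 17 Kupffer cell and macrophage markers had a called interaction (13 at an unadjusted p under 0.05; 11 adjusted over the list alone), and the list's adjusted p was 3.45e-12 by camera and 0.268 with an estimated correlation. In all 30 probe sets were called, 14 positive and 16 negative, with 1346 at an unadjusted p under 0.05. The count was 19 without C57BL/6J male 3 and 19 without KK male 2.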

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

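The tests in the paragraphs on KK females and on Kupffer cell and macrophage markers, and those on the partners and the probes of Eif4a1, Sarnp and Capza1, were chosen only after the result was seen, while those on other splits and on the direction of the largest calls were fixed earlier.

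Limma called an interaction for 18 genes named by the rule, by their list or after their values were seen. These stand here for a possible difference of the strain effect between females and males. Given as the strain difference in males minus that in females (log2), the positive values were Cyp2b13 5.08, Moxd1 3.40, Cyp2a22 3.09, Cyp17a1 2.96, Atp6v0d2 2.51, Cish 1.79, Serpina1d 1.66, Mogat1 1.0 and Car3 0.64. The negative values were Etnppl -1.10, Cyp2c39 -1.68, Mup20 -1.86, Cyp4a10 -2.39, Bcl6 -2.73, Hsd3b5 -3.84, Cyp4a14 -4.33, Cyp4a12a -6.31 and Cyp4a12b -6.59. Cish and Mup20 were named after their values were seen. The adjusted p of Mup20 was 0.0164, but 0.0512 without C57BL/6J male 2, 0.0533 without C57BL/6J male 3, and 0.051 without KK male 1 or KK male 2. Mogat1, Car3 and Etnppl, each the only called interaction of its list, missed the threshold in at least 1 omission of an array. Hsd3b5 and Cish missed it in several omissions, and Cyp17a1 without any one array other than C57BL/6J male 1. For the interaction calls as a whole, chance could not be excluded, as set out below. In males of both strains Cyp2b13 lay at the background level, so a fall there could not have been seen.

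With its preset correlation, camera gave the interaction an adjusted p under 0.05 for 14 of 31 lists, which stand here for a possible difference between the sexes. With an estimated correlation 0 of the 31 lists passed, with an adjusted p of 0.165 to 0.735 for these 14, and fry passed 1, the male-biased liver genes (0.0149). At the preset correlation the adjusted p was 1.44e-24 for male-biased liver genes, 2.66e-12 for female-biased liver genes, 3.45e-12 for Kupffer cell and macrophage markers, 0.000118 for MHC class I and class II genes, 0.000431 for periportal hepatocyte genes and 0.000448 for glucose metabolism and insulin signalling. It was 0.00107 for cholesterol synthesis and SREBP2 targets, 0.00107 for bile acid synthesis and transport, 0.00158 for the unfolded protein and integrated stress response, 0.00245 for the circadian clock, 0.0109 for PPARgamma targets and lipid droplets, 0.0161 for pericentral hepatocyte genes, 0.0194 for white adipose tissue markers and 0.0461 for fatty acid oxidation and PPARalpha targets. In single omissions of an array 6 of them missed the threshold: cholesterol synthesis and SREBP2 targets without C57BL/6J female 2 (0.109) or KK male 3 (0.0573), PPARgamma targets and lipid droplets without C57BL/6J male 2 (0.159), the unfolded protein and integrated stress response without C57BL/6J female 3 (0.0671) or KK male 3 (0.0899), the circadian clock without C57BL/6J male 3 (0.0518), pericentral hepatocyte genes without C57BL/6J female 2 (0.0902), C57BL/6J male 2 (0.161), KK female 2 (0.0649) or KK male 3 (0.0899), and fatty acid oxidation and PPARalpha targets without C57BL/6J female 1 (0.832), C57BL/6J male 2 (0.17), KK female 1 (0.148), KK female 2 (0.165), KK male 1 (0.155) or KK male 2 (0.082). In this last list the median of 0.04 and the mean of -0.33 differed in sign.

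Other splits of the samples were counted for each comparison. With the strain relabelled within each sex, 1 of 100 splits, the real one, gave as many calls (2488, against 39 in the highest other). That share is under 0.05 and argues against chance as the source of the strain difference. The other splits mix the strains within groups, which widens the spread and lowers their counts. Relabelling also cannot separate strain from a batch or litter that the labels do not give. The 6 arrays of 2 groups make 10 splits, which are too few for a share under 0.05. The real split gave the most calls: 1378 against 0 in the highest other for strain in females (1 of 10), 1092 against 0 for strain in males (1 of 10), 219 against 0 for sex in C57BL/6J (1 of 10) and 460 against 5 for sex in KK (1 of 10). For the interaction, 2 of 100 assignments of the residuals, the real one included, gave at least as many calls as the real 30. The share is under the 0.05 of the rule set for it. It cannot exclude chance, however, because the residuals carry a structure of the samples. The highest other gave 828, which points to that structure. It placed the 4 arrays with replicate number 3 on one side and the 4 with number 2 on the other, and 5 of the 6 arrays with the largest interquartile range on one side (49.8% of its variance), so it followed both the number and the range.

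Of 18 male-biased liver genes 10 were called higher in KK females than in C57BL/6J females, and of 18 female-biased ones 10 lower, but no list test was run in females alone. Over both sexes the adjusted p by camera was 0.455 with an estimated correlation for each list. At the preset correlation it was 8.51e-09 for the male-biased and 2.94e-07 for the female-biased list, and fry gave 0.00193 and 0.00585. Male RNA in the KK female arrays would raise the Y-linked genes, whose median strain difference in females was 0.083, far under the 3.31 to 4.10 by which Eif2s3y and Uty differed between the sexes. A probe sequence difference in Cyp4a12a and Cyp4a12b alone could not account for the 18 other list genes called in their list's direction. These calls are part of the pattern itself, so they are no independent test of it. A shift of the whole male programme is argued against by 4 male-biased genes that stayed below the midpoint of the C57BL/6J sexes. What stays open, as a hypothesis, is a strain difference in a part of the sex-biased programme, whose cause was not tested.

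In KK, the probe sets of Eif4a1, Sarnp and Capza1 fell, and lower calls outnumbered higher ones. Sequence variants under probes designed on C57BL/6J would make the largest strain calls lower in KK: of the 200 largest, 55% were lower (95% confidence interval 47.8% to 62.0%), which leaves variants open, and the excess of lower calls was gone after quantile (48.9%) and loess (49.6%) normalization. The bound set beforehand, the 69.5% lower in males among the 200 largest sex calls, was wrong, since that share reflects sex and not what variants would give. For the 3 genes themselves, variants and a loss of the transcript could not be told apart, as both give the same fall in both sexes (0 of the 3 had a called interaction) and no probe-level values were available. A joint fall of the partners of these genes is argued against by the median strain difference of 16 measured partners, -0.078, with a range of -0.40 to 0.90.

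In KK males, Kupffer cell and macrophage markers were lower than in KK females. Without KK female 1 the median difference was -0.855, and with the interquartile range of the arrays as a covariate -0.91, so neither was the whole source, although the calls fell from 13 of 17 to 5 and to 8. A smaller share of all cells other than hepatocytes would lower the markers of each such cell type. The sinusoidal endothelial markers differed by -0.263 (-0.156 without KK female 1), a gap to the Kupffer list of 0.73 (SE 0.16) per array. This gap cannot decide the question, since the lists may differ in how far hepatocytes also transcribe their markers. The sinusoidal markers were lower as well. A sex difference of KK mice in the number or the state of macrophages stays open, as does that smaller share of cells. Both are hypotheses that these data may not settle, since cells were not counted.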

How the results depend on the processing

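The array interquartile range as a covariate was the alternative chosen only after the data were seen. Results were the number of calls of each comparison, the correlation of the strain difference between the sexes, the number of lists past camera, and 199 single gene results. Among the latter 175 passed the threshold, of which 162 did so with every array left out in turn, 166 under every other alternative run for them and 160 under both kinds. No result that passed the threshold in the main fit or in the alternative reversed its direction. Of the 199, 160 could be tested among probe sets above the median mean and 46 with only the 2 groups compared, and the fold of at least 1.5 was applied to counts alone. Counts moved by over 1.5 times as follows, and the cause was not tested except where the setting itself tests fewer arrays or demands more. Array weights gave 2423 calls for strain in males, 363 for sex in C57BL/6J, 2058 for sex in KK, 77 for the interaction and 9 lists for the interaction. A fold of at least 1.5, a stricter demand, left 501 calls for strain over both sexes, 558 in females, 467 in males and 259 for sex in KK. With only the 2 groups compared, which leaves fewer arrays, sex in KK had 190. With an estimated correlation camera passed 0 lists for strain, 2 for sex and 0 for the interaction. Fry passed 1 list for the interaction, while its counts of 15 for strain and 13 for sex moved by less. With the array interquartile range as a covariate there were 2329 calls for strain in females, 1673 in males and 392 for sex in C57BL/6J. With each array left out in turn, where a group of 3 was left with 2, the counts ranged from 2004 to 2371 for strain over both sexes, 905 (without KK female 1) to 1412 in females, 662 (without KK male 1) to 1163 in males, 142 (without C57BL/6J male 3) to 225 for sex in C57BL/6J, 160 (without KK female 1) to 512 for sex in KK, and 19 (without C57BL/6J male 3 or KK male 2) to 35 for the interaction. In the same omissions the correlation between the sexes ranged from 0.572 to 0.686, and the lists from 11 to 16 for strain, 16 to 20 for sex and 12 to 15 for the interaction. The sample titles carry a replicate number, but the labels pair no mice: 10 of 18 pairs of arrays with the same number correlated above 0.1 after the group means were removed (range -0.356 to 0.477, median 0.109, against a median of -0.0512 for other pairs), and 8 of 12 arrays had their highest mean correlation with arrays of other groups at their own number. The latter is a hint of a shared structure from the data and not the design. With the number as a block the counts were 3113, 1765, 1477, 259, 624 and 41 in the order above, and the lists 11, 17 and 13. Quantile and loess normalization turned the sign of 24 list medians, all of them small, and of 0 called list members, and changed the share of lower calls from 53.8% to 48.9% and 49.6% for strain over both sexes, and from 67.8% to 58.1% and 63.6% for sex in KK. Other background corrections were not run, as they need the scanner files. Near the level of absent transcripts, a mean of 4.19, RMA compresses differences, so the fold of genes such as Eif4a1, Sarnp and Cyp2b13 is limited by the background.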

Other observations

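The tests of neighbouring genes and of other fasting-induced genes were chosen only after the result was seen.

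Gene families, chosen after their values were seen, differed within themselves between the strains. Of 8 measured Akr1c genes, 1 rose in KK and 4 fell: Akr1c18 rose by 4.92, while Akr1c12 fell by 2.61, Akr1c19 by 0.53 and Akr1c20 by 0.45. Of 17 carboxylesterase genes 6 fell, among them Ces2a (-1.94) and Ces3b (-1.06), and 1 rose, Ces1e (0.56). Of 13 Cyp2c genes 2 rose and 4 fell, with Cyp2c39 at 2.94 and Cyp2c38 at -1.49. Of 6 Cyp4a genes the near-identical Cyp4a12a and Cyp4a12b rose and Cyp4a10, Cyp4a14 and Cyp4a31 fell. Of 19 glutathione S-transferase genes 6 rose and 5 fell, with Gstp3 at 5.08 and Gsto1 at -0.83, and both measured vanin genes fell. Paralogs in these families are similar in sequence, so the values are uncertain as to the gene. No called member of these families turned its sign with quantile or loess normalization.

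Protease inhibitors and transporters, also chosen after their values were seen, differed as well. Of 19 Serpina genes 5 rose and 3 fell: Serpina12, which encodes the adipokine vaspin, rose by 1.72 and Serpina11 by 1.53, while Serpina1d fell by 2.53. Of 48 ABC transporter genes 4 rose and 9 fell, with Abca3, a phospholipid transporter, at 1.30, the peroxisomal Abcd2 at -2.10, Abca8a at -0.72 and Abcc6 at -0.68. Of 18 sulfotransferase genes 4 fell: Sult3a1 (-1.59), Sult1a1 (-0.57), Sult1d1 (-0.46) and Sult2a8 (-0.25).

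Genes called between the strains lay next to each other. Of these genes, 18.1% were followed on the chromosome by another called gene, against a mean of 12.5% and a highest value of 14.7% in 1000 permutations of the calls. Sex calls, for which no strain haplotype is needed, also lay together (10.97% against a mean of 3.96%). Shared haplotype blocks and clusters of related genes may each account for this, and these values cannot tell one from the other. Of 418 adjacent pairs 253 had the same direction.

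A weaker fasting response in KK males was a candidate explanation for the lower Cyp4a10, Cyp4a14, Cyp4a31 and Vnn1. Of 11 other genes known to be induced by fasting, the median strain difference in males was -0.082, from -0.73 for Igfbp1 to 0.56 for Pdk4, and 1 was called lower, Slc25a20 (-0.46). Differences had both signs, but 0 of these genes were called higher. All mice went without food for 4 hours and there was no fed group. A fasting response could therefore not be measured, and the hypothesis stays open.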
